A study of Homo sapiens with 8 samples.

How the data were processed

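RNA-seq counts of 8 libraries were analysed: 2 control and 2 gamitrinib libraries of each of the glioma lines M059K and LN229, with groups and replicate numbers taken from the sample titles. The titles gave gamitrinib at 5 µM and 48 h, while the treatment protocol in the labels gave 6-thio-dG at 5 µM or DMSO for 72 h, and this conflict was not resolved. The values are raw read counts per Ensembl gene, as deposited by the authors, 1 file per library and not normalized. Per the submitters' processing notes, the tools were FastQC 0.11.5, Trim Galore 0.6.5 and HTSeq 0.12.4, and the build was GRCh38. The aligner, the annotation release and the strand setting were not given in the sources used here, so reads of overlapping and antisense genes may not have been separated. Near-identical genes such as HSPA1A and HSPA1B, and genes with many pseudogenes, are uncertain for the same kind of reason, since reads that matched several places were set apart by the counting program.

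The files held 18952 genes, of which 18749 were named by the gene name table and 18793 were in GENCODE release 29, 18727 of them as protein-coding. Coordinates are those of GENCODE 29 on GRCh38. No read was counted in any library for 1825 genes. None of the 18952 genes in the files was mitochondrially encoded, so the list of 13 protein-coding genes of the mitochondrial genome was not analysed here. Counts assigned to genes were 26475237 and 24672821 in M059K control, 25309860 and 25315121 in M059K gamitrinib, 25970093 and 25800530 in LN229 control, and 22483186 and 25424773 in LN229 gamitrinib libraries. Entries that name no gene stayed out of library sizes and tests: 9.89 to 14.02% of reads overlapped no feature, 1.23 to 1.48% were ambiguous and 3.0 to 3.69% did not align uniquely. The 10 most abundant genes held 3.63 to 5.7% of gene counts. Floors cover counting error only.

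Tests used R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (14056 genes), scaled by TMM (factors 0.91 to 1.06) and fitted with the robust quasi-likelihood model over all 8 libraries in 4 groups, which share the estimate of the spread. The common dispersion was 0.00192 (biological coefficient of variation 4.38%). Contrasts were gamitrinib against control in each line, and the LN229 effect minus the M059K effect. All gene p-values are two-sided and Benjamini-Hochberg adjusted over the tested genes, with a threshold of 0.05. Fitted log2 fold changes use a prior count of 0.125, and the log2 CPM values behind the list tests and correlations one of 2. Each standard error is the absolute log2 fold change divided by the square root of its quasi-likelihood F. CPM values are means of the 2 libraries of a group, with their SD. Replicates differed by more than counting noise, with a chi-square per degree of freedom of 3.22 to 4.60.

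Of 38 gene lists fixed before the data were examined, 36 had at least 5 tested members. They were tested with camera (limma 3.58.1, preset correlation 0.01), with adjustment over the 36 lists of a comparison, and again with a correlation estimated for each list. No list call in any comparison held with the estimated correlation, where the smallest adjusted p was 0.103 in M059K, 0.065 in LN229 and 0.0586 for the difference. That version also rests on the 4 residual degrees of freedom, so a lost call need not reflect correlation between genes. For the difference, the hypoxia list went from an adjusted p of 5.48e-08 to 0.0586 although its estimated correlation was -0.03, below the preset. Other lists had estimates far above the preset, with 0.46 for ribosomal proteins, 0.29 for interferon-stimulated genes, 0.24 for mitosis and 0.22 for heat shock. For such lists correlation between genes may account for the lost calls. Each list was also counted with p-values adjusted over the list alone. The overlap between the lines was tested with Fisher's exact test, two-sided.

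Named genes came from a rule also fixed before the data were examined. In each line it took the 10 largest rises and the 10 largest falls among genes that passed, with a mean of at least 5 CPM and every gamitrinib library on one side of every control library. For each list that passed it took the 3 members with the smallest p in its direction and 1 in the opposite direction. For each other list it took the member with the smallest p, if that passed. HSP90AA1, HSP90AB1, HSP90B1, TRAP1, HSPA1A, DDIT3, ATF4, PPARGC1A and TFAM were always included. For the difference between the lines, and for genes changed in both, it took the 6 largest in each direction. Of the genes the rule selected, 86 are printed, and this selection was made after values were seen. Some genes the rule selected are withheld and not reported here. An earlier selection had dropped PKM, DDX21, EIF2AK2, ID3, IL1RL1 and PTPRZ1, whose results depend on the scaling, on single libraries or on a group without reads. These were put back so that the printed genes would not look more stable than the rule's own.

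Alternatives fixed beforehand were RLE, upper quartile and library size scaling, other filters on low counts, DESeq2 1.42.0, limma-voom, the 4 libraries of a line alone, a 1.5-fold minimum, a dispersion that is not robust, replicate blocks, and leaving out each library in turn. For lists they also included the rotation test fry and a preranked camera test. The procedure was tested on simulated counts with changes planted in 50 genes per fold in a single line, with the spread taken from these libraries. All other genes were unchanged there, whereas 59.5% of tested genes were called in M059K and 61.6% in LN229. The shares that follow apply to that setting and need not hold in the data. In M059K it recovered 56% of genes changed 1.25-fold, 84% at 1.5-fold, 92% at 2-fold and 96% at 4-fold, with 8 false calls among 13680 unchanged genes. In LN229 these shares were 58, 68, 88 and 98%, with 13 false calls among 13711. The test of the difference recovered less of small changes. For changes planted in M059K the shares were 18, 68, 80 and 94%, with 12 false calls among 13680, and for those planted in LN229 they were 26, 50, 80 and 86%, with 10 among 13711.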

Results

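The data were 8 RNA-seq libraries of the glioma cell lines M059K and LN229, both established from human glioblastomas. Each line was cultured for 48 h with gamitrinib at 5 µM or as a control, and each of the 4 groups held 2 libraries. Gamitrinib is a mitochondria-targeted inhibitor of HSP90 chaperones that joins a geldanamycin-type HSP90 inhibitor to a cationic group taken up by mitochondria, where the HSP90 paralog TRAP1 resides. The series title names mitochondrial biogenesis and tumour bioenergetics in glioma as its subject. The labels were not uniform: sample titles and the series design gave gamitrinib, whereas the treatment protocol text gave 6-thio-dG at 5 µM for 72 h, and some fields called the controls untreated where the design called them DMSO-treated. Groups here follow the titles, so which compound and time the treated groups stand for rests on those titles. Counts assigned to genes ranged from 22483186 to 26475237 per library, and 14056 genes were tested. The labels did not say that the libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

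Replicates had a Pearson r of 0.993 across genes on the log2 CPM scale in every group. Control and gamitrinib libraries had an r of 0.964 to 0.966 in M059K and 0.955 to 0.958 in LN229, whereas libraries of different lines had an r of 0.768 to 0.811. Genes are not independent replicates, so these coefficients describe the libraries. Both gamitrinib libraries lay on the same side of both control libraries for 10804 of the 14056 tested genes in M059K and 11195 in LN229, where chance order gives 33.3% of genes.

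The first comparison asked how M059K cells responded to gamitrinib. Genes of the HSF1 heat shock list and of the ATF4 and CHOP list rose, and genes of the extracellular matrix and of glycolysis fell. No list call in M059K held with an estimated correlation, where the smallest adjusted p was 0.103. HSPA1B, an inducible cytosolic HSP70 gene (ENSG00000204388, chromosome 6, 31827735 to 31830255, GRCh38), rose from 122 ± 1.06 to 2128 ± 101 CPM (mean ± SD, n = 2), a log2 fold change of 4.12 ± 0.04 (SE; adjusted p = 3.92e-55). THBS1, which encodes the matrix glycoprotein thrombospondin-1 (ENSG00000137801, chromosome 15, 39581079 to 39599466), fell from 5243 ± 117 to 1157 ± 5.55 CPM (log2 fold change -2.18 ± 0.03, adjusted p = 3.92e-55). In all, 4073 genes rose and 4297 fell, of which 866 and 981 changed at least 2-fold. With library size alone as the scaling, the median of all genes shifted by 0.20 on the log2 scale and the split became 6255 higher and 2788 lower (69.2% higher instead of 48.7%), so the direction of small M059K changes depends on the scaling.

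Of 34 heat shock genes controlled by HSF1, 33 rose and none fell in M059K (34 rose when adjusted over the list alone; median log2 fold change 0.81, camera adjusted p = 1.63e-12). This call was lost with the correlation estimated from the data (adjusted p = 0.182 with an estimated correlation). The cytosolic HSP90 genes HSP90AA1 and HSP90AB1 rose by 1.07 ± 0.04 and 0.80 ± 0.03, and the constitutive HSP70 gene HSPA8 and the HSP40 co-chaperone gene DNAJB1 rose by 1.03 and 1.43. HSP90B1, the HSP90 paralog of the endoplasmic reticulum, fell by 0.80, and TRAP1 had a log2 fold change of -0.11 ± 0.06 that did not pass (adjusted p = 0.0862), and 0.09 with library size alone (adjusted p = 0.161). HSPA1A rose with HSPA1B (4.18 ± 0.06). Both genes are nearly identical in sequence, so how reads divide between them is uncertain.

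Among 42 targets of ATF4 and CHOP, the integrated stress response list, 38 rose and 3 fell in M059K, over all genes and adjusted over the list alone alike (median 1.28, camera adjusted p = 5.65e-16; adjusted p = 0.124 with an estimated correlation). TRIB3, a pseudokinase induced by CHOP, rose from 55.9 ± 2.56 to 344 ± 4.59 CPM (2.62 ± 0.05). ASNS, which encodes asparagine synthetase, rose by 2.19, and the transcription factor genes DDIT3 (CHOP) and ATF4 rose by 1.28 and 0.67. ALDH18A1, a proline synthesis gene in the same list, fell by 0.83. INHBE, an inhibin subunit gene, rose by 3.74 ± 0.08. Of 28 targets of the antioxidant regulator NRF2, 21 rose and 1 fell in both counts, over all genes and adjusted over the list alone (camera adjusted p = 1.12e-07; adjusted p = 0.179 with an estimated correlation). NQO1, a quinone reductase gene (ENSG00000181019, chromosome 16, 69706996 to 69726951), rose from 69.0 ± 0.463 to 421 ± 0.922 CPM (2.61 ± 0.04), and the ferritin light chain gene FTL rose by 1.69. Interferon-stimulated genes also moved up, with 26 of 35 higher and 1 lower (27 and 1 adjusted over the list alone; camera adjusted p = 1.42e-05; adjusted p = 0.48 with an estimated correlation). EIF2AK2, the double-stranded RNA-activated kinase PKR, rose by 0.76, IFI44L by 1.15 and IFIT2 by 1.20. In the other direction, OASL fell by 0.50, a call lost without M059K control replicate 1 (-0.37, adjusted p = 0.115) or gamitrinib replicate 1 (-0.34, adjusted p = 0.122), and with library size alone (-0.29, adjusted p = 0.0923). In the autophagy and lysosome list 23 of 44 genes rose and 7 fell (24 and 8 adjusted over the list alone; camera adjusted p = 0.0149; adjusted p = 0.197 with an estimated correlation). The autophagy receptor gene SQSTM1 rose by 1.15.

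In the extracellular matrix and TGF-beta list, 35 of 37 genes fell and 1 rose in M059K, with the same numbers adjusted over the list alone (median -1.35, camera adjusted p = 2.95e-16; adjusted p = 0.103 with an estimated correlation). The fibronectin gene FN1 fell from 9154 ± 82.0 to 2517 ± 41.4 CPM (-1.86 ± 0.03), and COL3A1, a fibrillar collagen gene (ENSG00000168542, chromosome 2, 188974320 to 189012746), fell from 3138 ± 32.1 to 725 ± 15.5 CPM (-2.11 ± 0.03). CEMIP, which encodes a hyaluronan-binding protein, had a log2 fold change of -4.01 ± 0.10, and ACTA2, smooth muscle actin, one of -3.55 ± 0.06. The urokinase gene PLAU (-3.86 ± 0.12) and the carbonic anhydrase gene CA9 (-3.78 ± 0.18) fell to a similar extent. Of 26 receptor tyrosine kinase and HSP90 client kinase genes, 17 fell and 5 rose, adjusted over the list alone as well (camera adjusted p = 0.00683; adjusted p = 0.182 with an estimated correlation). PDGFRB fell by 2.02 and MET fell by 1.27.

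The glycolysis, hypoxia, cholesterol and tricarboxylic acid cycle lists fell in M059K. Of 22 glycolysis genes, 21 fell and 1 rose (the same adjusted over the list alone; median -0.82, camera adjusted p = 4.86e-09; adjusted p = 0.182 with an estimated correlation). LDHA, lactate dehydrogenase A, fell from 1676 ± 65.2 to 453 ± 13.7 CPM (-1.89 ± 0.03), and GAPDH and the pyruvate kinase gene PKM fell by 0.92 and 0.91. In the hypoxia list 18 of 25 genes fell and 4 rose, also when adjusted over the list alone (camera adjusted p = 0.00128; adjusted p = 0.144 with an estimated correlation). The glucose transporter gene SLC2A1, which is in the glycolysis list too, fell by 1.40. VEGFA, another member, had 391 ± 9.68 CPM in control and 410 ± 28.5 CPM in gamitrinib libraries, without a call. It was called higher with upper quartile scaling (0.11, adjusted p = 0.0303) and with library size alone (0.27, adjusted p = 1e-06). Of 25 cholesterol synthesis and uptake genes, 19 fell and none rose (21 fell when adjusted over the list alone; camera adjusted p = 3.68e-06; adjusted p = 0.144 with an estimated correlation). SREBF2, the regulator of this pathway, fell by 1.13. The tricarboxylic acid cycle list had 16 of 23 genes down and 2 up, adjusted over the list alone as well (camera adjusted p = 0.000936; adjusted p = 0.246 with an estimated correlation), among them OGDH (-1.22) and IDH2 (-0.93). Of 50 mitosis genes, 30 fell and 7 rose, adjusted over the list alone likewise (camera adjusted p = 0.00388; adjusted p = 0.52 with an estimated correlation), and the list's median was small at -0.23. MKI67, the Ki-67 proliferation marker, fell by 0.81, and the mitotic kinesin gene KIF20A by 0.67, whereas the kinase gene NEK2 rose by 0.61. With library size alone as the scaling, 16 mitosis genes rose and 15 fell, around a median of -0.03. Under it, 6 tricarboxylic acid cycle genes rose and 12 fell (median -0.19 instead of -0.39).

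The other lists did not pass the camera test in M059K. Counts adjusted over the list alone are given for those where they differed from the counts over all genes. Nuclear-encoded complex I genes had 5 of 36 up and 6 down (4 and 4 adjusted over the list alone; adjusted p = 0.739), complexes II to IV 4 of 26 up and 11 down (adjusted p = 0.351), and ATP synthase 1 of 18 up and 9 down (adjusted p = 0.0596), although ATP5F1A itself fell by 0.86. The ATP synthase list passed without M059K control replicate 1 (adjusted p = 0.0425) or gamitrinib replicate 2 (adjusted p = 0.0313). The mitochondrial biogenesis list had 6 of 25 genes up and 6 down (adjusted p = 0.82). TFAM, the mitochondrial DNA packaging factor, had a log2 fold change of 0.07 ± 0.06 (adjusted p = 0.35), which became 0.27 with library size alone (adjusted p = 8.28e-05). PPARGC1A, a coactivator of biogenesis, rose by 1.22 ± 0.30 from 2.64 CPM. Mitochondrial ribosome genes had 22 of 76 up and 17 down (21 and 17 adjusted over the list alone; adjusted p = 0.478), and mitochondrial chaperones and proteases 6 of 23 up and 12 down (6 and 13; adjusted p = 0.369). Mitochondrial import genes had 13 of 25 up and 5 down (adjusted p = 0.1), and this list passed without M059K gamitrinib replicate 1 (adjusted p = 0.0365). DNA replication genes had 18 of 57 up and 16 down (adjusted p = 0.582), and homologous recombination and Fanconi genes 17 of 35 up and 7 down (adjusted p = 0.225). For p53 targets 15 of 29 rose and 6 fell (15 and 7 adjusted over the list alone; adjusted p = 0.0632), and for the BCL-2 family and death receptors 12 of 23 rose and 6 fell (adjusted p = 0.082). Cytosolic ribosomal proteins had 21 of 72 up and 30 down (adjusted p = 0.525), ribosome biogenesis 5 of 37 up and 16 down (adjusted p = 0.104) and aminoacyl-tRNA synthetases 11 of 20 up and 5 down (adjusted p = 0.103). The endoplasmic reticulum unfolded protein response had 12 of 35 up and 13 down (13 and 13 adjusted over the list alone; adjusted p = 0.95), and its median of 0.01 and mean of 0.06 had the opposite sign to the test. The NF-kB list had 4 of 26 up and 7 down (adjusted p = 0.194), immediate early genes 7 of 29 up and 14 down (adjusted p = 0.168) and telomere genes 5 of 22 up and 4 down (5 and 3 adjusted over the list alone; adjusted p = 0.491). Neural and glial lineage genes had 4 of 26 up and 13 down (adjusted p = 0.0811), and the transcriptional regulator gene ID3 fell by 1.77. Marker lists of other cell types held few tested genes. They had 1 of 5 up and 2 down for microglia (adjusted p = 0.95), 3 of 12 up and 2 down for neurons (3 and 1 adjusted over the list alone; adjusted p = 0.95), and 1 of 9 up and 4 down for endothelium (adjusted p = 0.527). Epithelial markers had 2 of 9 up and 4 down (adjusted p = 0.491). For oligodendrocytes 0 of 10 rose and 5 fell (adjusted p = 0.129), and this list passed without M059K control replicate 1 (adjusted p = 0.0425). The sign of the median, the mean and the test did not match for telomere genes in both lines, or for microglia and neuron markers in M059K. Of the blood cell markers 2 were tested, and none of the listed genes had a group mean above 1.13 CPM.

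Many of these M059K counts depended on the scaling, since library size alone shifted the median of all genes by 0.20. Under it ribosomal proteins had 49 genes up and 7 down (median 0.18 instead of -0.03), and ribosome biogenesis 18 up and 9 down (0.11 instead of -0.10). Complex I had 21 up and 0 down (0.17 instead of -0.04), complexes II to IV 11 up and 5 down (0.12 instead of -0.08), and ATP synthase 6 up and 4 down (0.05 instead of -0.15). DNA replication had 36 up and 6 down (0.26 instead of 0.05), and homologous recombination and Fanconi genes 23 up and 1 down. The mitochondrial ribosome had 44 up and 8 down, biogenesis 13 up and 2 down, and mitochondrial chaperones and proteases 7 up and 4 down (median 0.04 instead of -0.17). Endoplasmic reticulum genes had 19 up and 12 down, NF-kB genes 7 up and 7 down, and telomere genes 12 up and 1 down. Immediate early genes had 10 up and 12 down (median 0.01 instead of -0.19), and neuron markers 4 up and 1 down (0.12 instead of -0.09). None of these lists passed the camera test under library size scaling. The uncalled lists that did pass under it were mitochondrial import (17 up, 1 down, adjusted p = 0.0156), neural and glial lineage genes (4 up, 12 down, adjusted p = 0.00214) and oligodendrocyte markers (0 up, 3 down, adjusted p = 0.0284). Neural and glial genes also passed with a 5 CPM filter (adjusted p = 0.0421) and with the preranked camera test on the quasi-likelihood statistic (adjusted p = 0.00227). The preranked test called p53 targets (adjusted p = 0.00649), aminoacyl-tRNA synthetases (adjusted p = 0.000377), immediate early genes (adjusted p = 0.0249) and epithelial markers (adjusted p = 0.00151) as well.

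**Figure D1:**
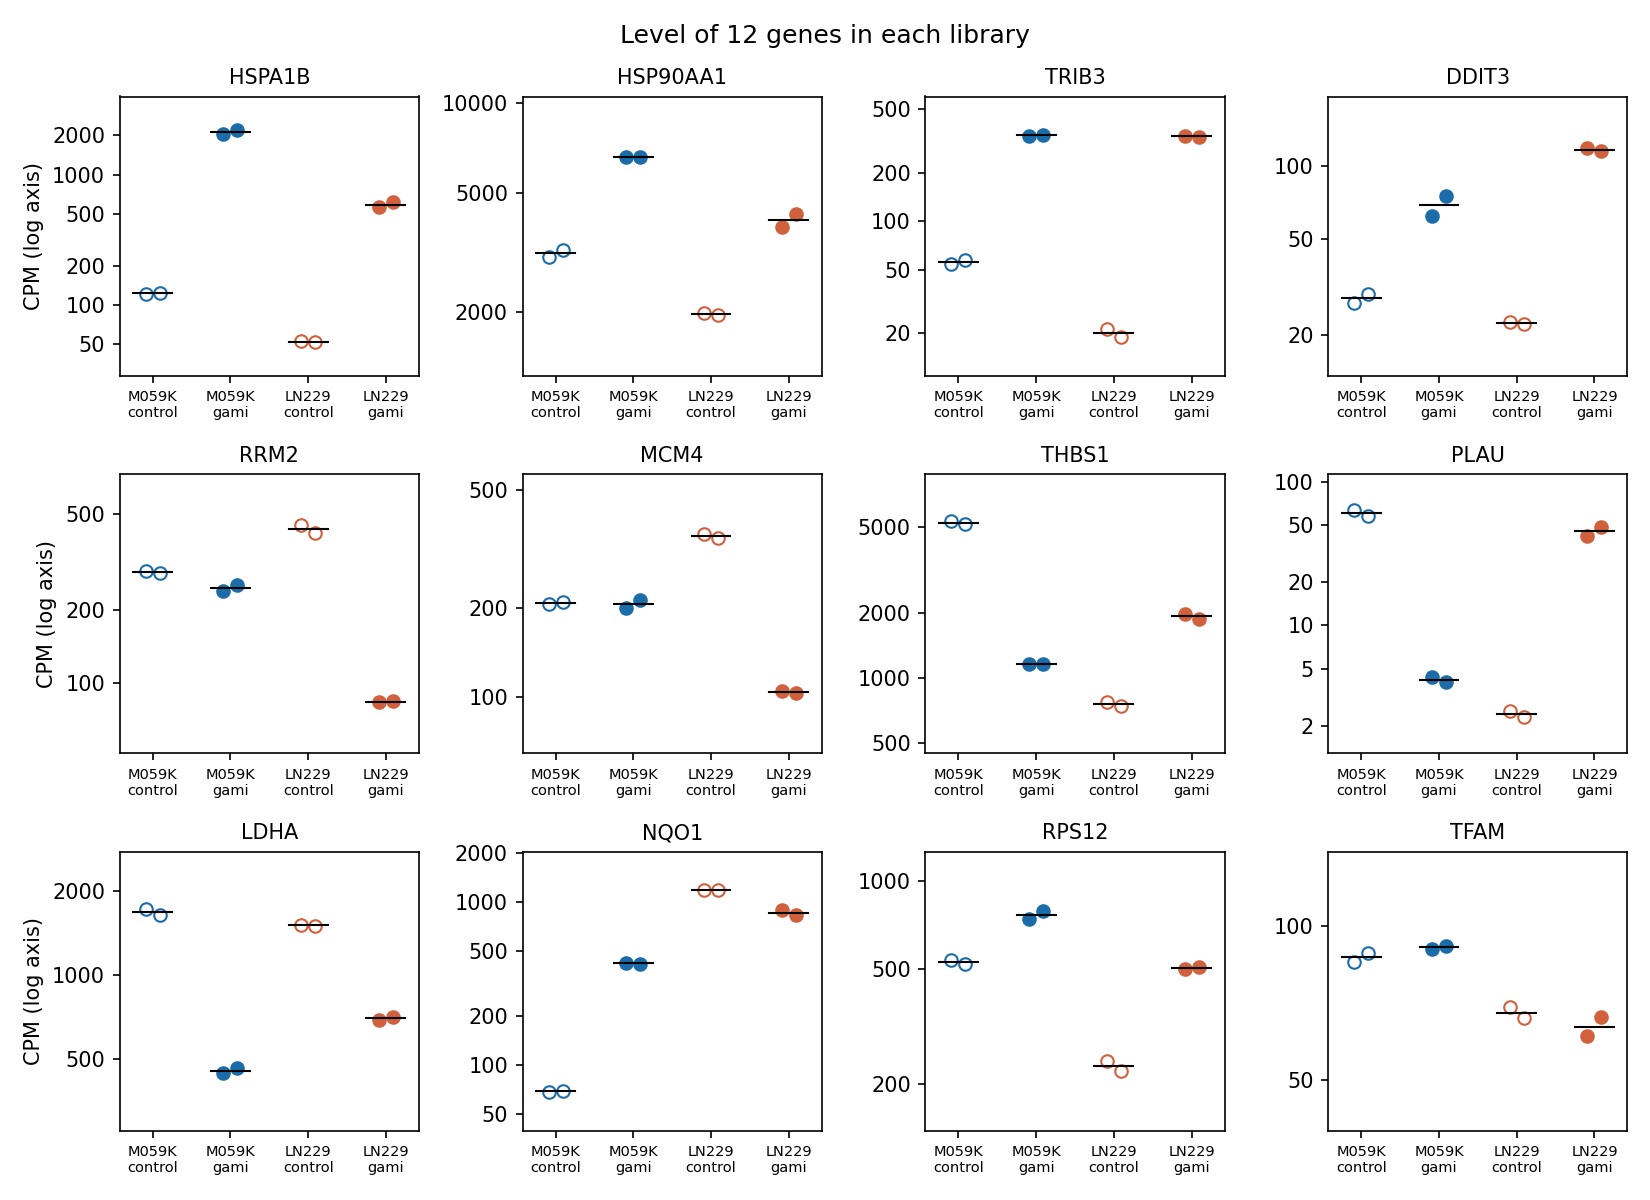
CPM (log axis) of 12 genes in each of the 8 libraries, with open circles for control, filled circles for gamitrinib and a black line at the mean of the 2 libraries of a group. HSPA1B and TRIB3 rose in both lines, RRM2 fell from 435 to 84.0 CPM in LN229 and had 288 and 248 CPM in M059K, and THBS1 and PLAU fell in M059K and rose in LN229.

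The second comparison asked how LN229 cells responded to the same treatment. Heat shock and ATF4 target genes rose here too, while genes of DNA replication and mitosis fell and ribosomal protein genes rose. In LN229 likewise no list call held with an estimated correlation (smallest adjusted p = 0.065). RRM2, the regulated subunit of ribonucleotide reductase (ENSG00000171848, chromosome 2, 10120698 to 10131419), fell from 435 ± 21.4 to 84.0 ± 0.148 CPM (log2 fold change -2.37 ± 0.05, adjusted p = 5.25e-48). TRIB3 (ENSG00000101255, chromosome 20, 362835 to 397559) rose from 20.1 ± 1.66 to 341 ± 2.90 CPM (4.08 ± 0.06, adjusted p = 7.59e-56). In all, 4368 genes rose and 4293 fell, of which 1227 and 1007 changed at least 2-fold. The split was 5243 and 3597 with library size alone, and 5213 and 3624 with upper quartile scaling, which each shifted the median of all genes to 0.10.

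Every gene of the DNA replication list fell in LN229, 57 of 57 over all genes tested and adjusted over the list alone (median -1.21, camera adjusted p = 7.06e-22; adjusted p = 0.065 with an estimated correlation). MCM4, a subunit of the replicative helicase (ENSG00000104738, chromosome 8, 47960185 to 47978160), fell from 349 ± 7.91 to 104 ± 1.08 CPM (-1.74 ± 0.05), and thymidine kinase TK1 fell by 1.80. Of 50 mitosis genes, 47 fell and none rose, adjusted over the list alone as well (median -0.88, camera adjusted p = 3.64e-15; adjusted p = 0.211 with an estimated correlation). MKI67 fell by 1.53 and KIF20A fell by 1.29. Homologous recombination and Fanconi genes had 26 of 35 down and 2 up in both counts, over all genes and adjusted over the list alone (camera adjusted p = 8.43e-06; adjusted p = 0.0767 with an estimated correlation), including FANCA (-1.69) and the exonuclease gene EXO1 (-1.65).

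The integrated stress response list had 40 of 42 genes up and 2 down in LN229, unchanged when adjusted over the list alone (median 1.66, camera adjusted p = 2.19e-18; adjusted p = 0.065 with an estimated correlation). ASNS rose by 2.74, DDIT3 by 2.39 and ATF4 by 1.23. STC2, which encodes the secreted glycoprotein stanniocalcin-2 (ENSG00000113739, chromosome 5, 173314713 to 173329503), rose from 10.9 ± 0.112 to 183 ± 4.27 CPM (4.07 ± 0.05). In M059K the STC2 level went from 1220 to 984 CPM, and so stayed above that of LN229. The stress-induced genes INHBE, ADM2 and NUPR1 rose by 5.90 ± 0.22, 5.59 ± 0.18 and 5.29 ± 0.13, all from at most 1.36 CPM in control cells, and without LN229 control replicate 1 the ADM2 value was 6.54. Under gamitrinib INHBE and NUPR1 had 14.2 and 37.5 CPM in LN229, against 158 and 234 CPM in M059K. ADM2 had 65.9 CPM in LN229 and 46.8 CPM in M059K. ALDH18A1 fell by 0.71 in LN229. Of 20 cytosolic aminoacyl-tRNA synthetase genes, 15 rose and 3 fell, the same adjusted over the list alone (camera adjusted p = 8.29e-05; adjusted p = 0.211 with an estimated correlation). GARS1 rose by 1.53 and WARS1 by 1.45, and VARS1 fell by 0.24. Heat shock genes rose in 29 of 34 cases and fell in 1, also adjusted over the list alone (median 0.86, camera adjusted p = 5.27e-09; adjusted p = 0.211 with an estimated correlation). HSPA1B rose by 3.49 ± 0.04, HSP90AA1 by 1.05, HSP90AB1 by 0.82 and HSPA8 by 0.94, and FKBP5, a co-chaperone of steroid receptors, fell by 1.13. TRAP1 rose by 0.15 ± 0.06 (adjusted p = 0.0213), a call lost without LN229 control replicate 1 (0.15, adjusted p = 0.0815), control replicate 2 (0.14, adjusted p = 0.113) or gamitrinib replicate 2 (0.12, adjusted p = 0.18).

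Cytosolic ribosomal protein genes rose in LN229, 69 of 72 with 1 lower, adjusted over the list alone as well (median 0.54, camera adjusted p = 1.8e-17; adjusted p = 0.252 with an estimated correlation). RPS12 rose from 231 ± 12.8 to 504 ± 4.12 CPM (1.12 ± 0.04), RPL37 by 0.91 and RPS18 by 0.83. These genes have many processed pseudogenes, and reads that matched several places were not counted. Ribosome biogenesis genes had 23 of 37 up and 5 down, in both counts, over all genes and adjusted over the list alone (camera adjusted p = 0.0111; adjusted p = 0.294 with an estimated correlation), and the nucleolar helicase gene DDX21 rose by 0.49. NRF2 targets had 19 of 28 up and 5 down (21 and 5 adjusted over the list alone; camera adjusted p = 0.000268; adjusted p = 0.211 with an estimated correlation). The haem oxygenase gene HMOX1 rose by 2.89, the thioredoxin reductase gene TXNRD1 by 1.65 and FTL by 1.46, while NQO1 fell by 0.46 from 1184 CPM. Interferon-stimulated genes had 27 of 35 up and 2 down (28 and 2 adjusted over the list alone; camera adjusted p = 4.53e-06; adjusted p = 0.289 with an estimated correlation). Here OASL rose by 3.18 from 0.622 CPM, IFI44L by 3.10 from 1.24 CPM and EIF2AK2 by 0.92, and IFIT2 fell by 1.21. Under gamitrinib OASL and IFI44L had 5.7 and 10.8 CPM in LN229, against 13.3 and 61.6 CPM in M059K.

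NF-kB and cytokine genes rose in 18 of 26 cases and fell in 4, the same adjusted over the list alone (camera adjusted p = 0.0079; adjusted p = 0.224 with an estimated correlation), including the interleukin-11 gene IL11 (1.19). The median was 0.82, or 0.62 without the 3 members that had no read in control libraries. The hypoxia list had 14 of 25 genes up and 3 down, adjusted over the list alone likewise (camera adjusted p = 0.0132; adjusted p = 0.211 with an estimated correlation). The angiogenic factor gene VEGFA rose from 33.0 ± 2.17 to 246 ± 0.676 CPM (2.90 ± 0.05), and CA9 rose by 2.57. Epithelial markers had 6 of 9 up and 2 down, adjusted over the list alone as well (camera adjusted p = 0.0469; adjusted p = 0.224 with an estimated correlation). In that list the keratin gene KRT7 rose by 1.89 and KRT14 fell by 0.91, and the call was lost without M059K control replicate 1 (adjusted p = 0.0562), M059K control replicate 2 (adjusted p = 0.056), M059K gamitrinib replicate 1 (adjusted p = 0.0658) or M059K gamitrinib replicate 2 (adjusted p = 0.0659). The cause was not tested. It was also lost with library size alone (adjusted p = 0.096) and a 5 CPM filter (adjusted p = 0.0651). KLHDC7B, a kelch domain gene, had no read in either LN229 control library and 30.8 ± 0.391 CPM under gamitrinib, at least 527-fold higher against a floor of 3 counts over both control libraries. IL1RL1, an interleukin-33 receptor gene, likewise had no LN229 control read and 3.67 ± 0.184 CPM under gamitrinib, at least 62.8-fold higher by the same floor. ASS1, argininosuccinate synthase, rose by 4.98 ± 0.20 from 0.991 CPM (5.94 without LN229 control replicate 1), and AKNA, a centrosomal protein gene, by 4.38 ± 0.10.

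Among the lists that fell in LN229, cholesterol synthesis and uptake had 23 of 25 genes down and none up, also adjusted over the list alone (median -0.99, camera adjusted p = 4.03e-10; adjusted p = 0.065 with an estimated correlation). SREBF2 fell by 1.66. Nuclear-encoded complex I genes had 22 of 36 down and 3 up, the same adjusted over the list alone (median -0.27, camera adjusted p = 0.00106; adjusted p = 0.294 with an estimated correlation). NDUFS6 fell by 0.71. ATP synthase genes had 13 of 18 down and 1 up, adjusted over the list alone too (camera adjusted p = 0.00302; adjusted p = 0.241 with an estimated correlation). ATP5F1A fell by 0.63. Complexes II to IV had 13 of 26 down and 3 up, likewise adjusted over the list alone (camera adjusted p = 0.0181; adjusted p = 0.276 with an estimated correlation). COX8A fell by 0.62. The tricarboxylic acid cycle list had 15 of 23 down and 1 up, in both counts, over all genes and adjusted over the list alone (camera adjusted p = 0.000665; adjusted p = 0.211 with an estimated correlation), and IDH2 fell by 1.48. Glycolysis genes had 14 of 22 down and 3 up, adjusted over the list alone as well (camera adjusted p = 0.00771; adjusted p = 0.308 with an estimated correlation). LDHA fell by 1.11, GAPDH fell by 0.93 and PKM fell by 0.89, and the hexokinase gene HK2 rose by 0.41. The endoplasmic reticulum list had 19 of 35 down and 9 up, adjusted over the list alone too (camera adjusted p = 0.0369; adjusted p = 0.289 with an estimated correlation). PDIA4, a disulfide isomerase gene, fell by 1.70 and HSP90B1 by 1.24, whereas HERPUD1, a degradation factor of that compartment, rose by 1.86.

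Neural and glial lineage genes had 14 of 26 down and 5 up in LN229, the same adjusted over the list alone (camera adjusted p = 0.00399; adjusted p = 0.173 with an estimated correlation). FABP7, a radial glia fatty acid binding protein, fell from 180 ± 1.33 to 10.6 ± 1.69 CPM (-4.09 ± 0.09), and the brevican gene BCAN rose by 2.52. PTPRZ1, a receptor phosphatase of glial precursors, fell from 230 ± 8.71 to 26.1 ± 0.36 CPM (-3.14 ± 0.07), and ID3 fell by 1.95. In M059K, PTPRZ1 had 0 control and 2 gamitrinib reads, so no fold is given there, and FABP7 had 0 reads in either group. Immediate early genes had 17 of 29 down and 8 up, adjusted over the list alone likewise (camera adjusted p = 0.0177; adjusted p = 0.211 with an estimated correlation). The transcription factor gene EGR1 fell by 3.35, and the signalling antagonist gene SPRY4 fell by 2.75. Some of these calls rested on the filter, scaling or statistic. The endoplasmic reticulum and NF-kB lists were lost with a 5 CPM filter (adjusted p = 0.0691 and 0.0651), and complexes II to IV with library size alone (adjusted p = 0.0548). With the preranked camera test on the quasi-likelihood statistic, complex I (adjusted p = 0.0545), complexes II to IV (0.155), NF-kB (0.0997) and ribosome biogenesis (0.0997) did not pass. Large falls outside these lists included the aggrecanase gene ADAMTS4 (-4.86 ± 0.15) and the matrix gene FREM1 (-4.66 ± 0.17). No call was made in LN229 for extracellular matrix genes (12 of 37 up and 19 down, 13 and 19 adjusted over the list alone, adjusted p = 0.306) or kinases (8 of 26 up and 14 down, 9 and 16 adjusted over the list alone, adjusted p = 0.191). The extracellular matrix list did pass with the preranked test (adjusted p = 0.00462). Nor was one made for autophagy and lysosome (21 of 44 up, 9 down, adjusted p = 0.152), p53 targets (11 of 29 up and 9 down, 11 and 10 adjusted over the list alone, adjusted p = 0.862) or the BCL-2 family (13 of 23 up, 5 down, adjusted p = 0.097). The same applied to mitochondrial biogenesis (6 of 25 up, 10 down, adjusted p = 0.542), the mitochondrial ribosome (25 of 76 up, 17 down, adjusted p = 0.542) and mitochondrial import (12 of 25 up, 7 down, adjusted p = 0.542). Scaled by library size, the biogenesis list had 8 up and 7 down (median 0.01 instead of -0.07). The mitochondrial ribosome then had 35 up and 12 down (median 0.13 instead of 0.05). Mitochondrial chaperones and proteases had 10 of 23 up and 5 down (10 and 6 adjusted over the list alone; adjusted p = 0.343), and telomere genes 8 of 22 up and 6 down (adjusted p = 0.829). TFAM had a log2 fold change of -0.09 ± 0.06 (adjusted p = 0.204). The mitochondrial protease gene LONP1 rose by 1.04. PPARGC1A rose by 1.40 ± 0.56 on 13 control and 34 gamitrinib reads (adjusted p = 0.0271), a call lost without LN229 control replicate 2 (1.09, adjusted p = 0.166), gamitrinib replicate 1 (1.31, adjusted p = 0.0887) or gamitrinib replicate 2 (1.49, adjusted p = 0.052). Markers of microglia (1 of 5 up, 0 down, 0 and 0 adjusted over the list alone, adjusted p = 0.829) and neurons (2 of 12 up, 7 down, adjusted p = 0.277) did not pass either. The same held for oligodendrocytes (2 of 10 up, 5 down, adjusted p = 0.968) and endothelium (5 of 9 up, 1 down, adjusted p = 0.542).

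**Figure D2:**
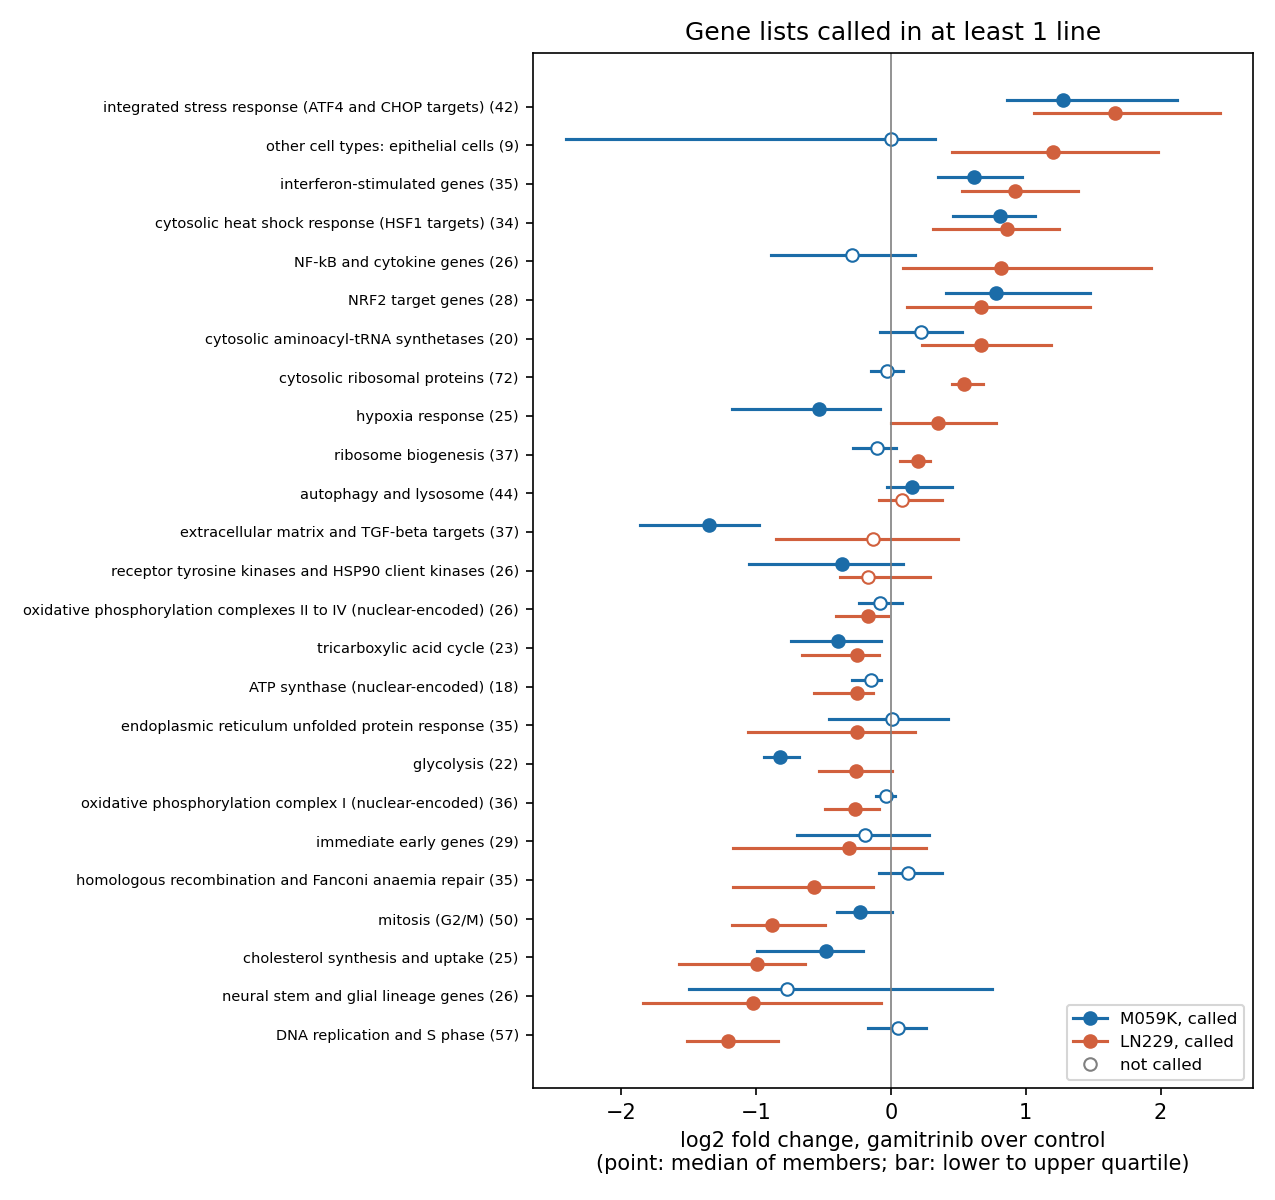
Median log2 fold change (point) and lower to upper quartile (bar) of the members of the 25 gene lists called in at least 1 line, with M059K in blue and LN229 in orange, filled where the camera test with a preset correlation passed; the number of tested genes is in parentheses. The replication list lies at -1.21 in LN229 and 0.05 in M059K, and the extracellular matrix list at -0.13 and -1.35.

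The third comparison asked which genes moved alike in both lines. Shared rises included the stress genes HSPA1A, HSPA1B and INHBE, given above, which rose by at least 3.49 on the log2 scale in each line. Shared falls included NREP, a regeneration-related neuronal protein gene, at -3.36 ± 0.05 in M059K and -2.55 ± 0.05 in LN229, and RGS4, a regulator of G-protein signalling, at -3.08 ± 0.08 and -4.48 ± 0.12. In all, 2079 genes rose in both lines, against 1266 for independent lists, and 2180 fell in both, against 1312 (Fisher's exact test across genes, two-sided, p = 4.1e-225 and 3.32e-251). A further 637 genes rose in M059K and fell in LN229 (1244 for independent lists), and 849 did the reverse (1335). The lines shared no control libraries, and genes are not independent, so these p-values describe these genes only. Across genes the fold changes of the lines had a Pearson r of 0.25 and a Spearman rho of 0.31. Scaled by library size, 3303 genes rose and 1318 fell in both lines.

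The last comparison tested whether the effect of gamitrinib differed between the lines, as the LN229 effect minus the M059K effect. The effect on replication and mitosis genes was lower in LN229 than in M059K, and that on matrix, hypoxia and ribosomal protein genes was higher. No list call for the difference held with an estimated correlation (smallest adjusted p = 0.0586). Higher and lower refer here to the difference in effect, not to levels. PLAU (ENSG00000122861, chromosome 10, 73909177 to 73917497) went from 60.9 ± 4.09 to 4.18 ± 0.234 CPM in M059K and from 2.43 ± 0.187 to 45.1 ± 4.67 CPM in LN229 (difference 8.08 ± 0.17, adjusted p = 3.25e-45). NRCAM, a neuronal cell adhesion gene (ENSG00000091129, chromosome 7, 108147623 to 108456717), went from 0.132 ± 0.128 to 1.41 ± 0.411 CPM in M059K and from 73.4 ± 0.148 to 6.92 ± 0.554 CPM in LN229 (difference -6.81 ± 0.44, adjusted p = 4.7e-21). With 6 reads in M059K control libraries the size of that difference is uncertain: it was -6.06 without M059K control replicate 1 and -8.35 without replicate 2. The difference was positive for 3472 genes and negative for 3421. Scaled by library size, the split was 2726 and 4465 (37.9% positive instead of 50.4%). All 1486 genes that moved in opposite directions passed this test, which nearly follows from their opposite calls in the same fit. Of the 4259 that moved in the same direction, 1905 passed.

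For DNA replication, the effect was lower in LN229 for 55 of 57 genes and higher for 1 (56 and 1 adjusted over the list alone; median -1.13, camera adjusted p = 3.36e-22; adjusted p = 0.0586 with an estimated correlation). The differences for RRM2 and MCM4 were -2.16 ± 0.06 and -1.73 ± 0.06, while in M059K their log2 fold changes were -0.21 ± 0.04 (adjusted p = 1.66e-05) and -0.01 ± 0.04 (adjusted p = 0.863). Under library size scaling those M059K values were -0.01 (adjusted p = 0.828) for RRM2 and 0.19 (adjusted p = 8.66e-05) for MCM4, and 36 of the 57 genes rose and 6 fell in M059K. Mitosis genes were lower in 42 of 50 cases and higher in 2, adjusted over the list alone as well (camera adjusted p = 6.27e-11; adjusted p = 0.303 with an estimated correlation). Homologous recombination genes were lower in 26 of 35 cases and higher in 3 (27 and 3 adjusted over the list alone; camera adjusted p = 1.53e-07; adjusted p = 0.0586 with an estimated correlation). Cholesterol genes were lower in 17 of 25 cases and higher in 2, in both counts, over all genes and adjusted over the list alone (camera adjusted p = 9.95e-05; adjusted p = 0.144 with an estimated correlation), and the difference for SREBF2 was -0.54. Complex I genes were lower in 17 of 36 cases and higher in 0, adjusted over the list alone likewise (camera adjusted p = 0.00178; adjusted p = 0.426 with an estimated correlation). Endoplasmic reticulum genes were lower in 19 of 35 cases and higher in 7 (20 and 7 adjusted over the list alone; camera adjusted p = 0.00912; adjusted p = 0.303 with an estimated correlation).

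All 72 ribosomal protein genes had a higher effect in LN229, also adjusted over the list alone (median 0.57, camera adjusted p = 3.88e-19; adjusted p = 0.317 with an estimated correlation). Hypoxia genes were higher in 21 of 25 cases and lower in 0, the same adjusted over the list alone (median 0.89, camera adjusted p = 5.48e-08; adjusted p = 0.0586 with an estimated correlation). VEGFA differed by 2.83 and CA9 by 6.35. Extracellular matrix genes were higher in 27 of 37 cases and lower in 6, adjusted over the list alone as well (camera adjusted p = 1.53e-07; adjusted p = 0.121 with an estimated correlation), and THBS1, which rose by 1.35 in LN229, differed by 3.53 ± 0.04. Aminoacyl-tRNA synthetases were higher in 17 of 20 cases and lower in 1, also adjusted over the list alone (camera adjusted p = 2.42e-05; adjusted p = 0.204 with an estimated correlation). Glycolysis genes were higher in 14 of 22 cases and lower in 1, the same adjusted over the list alone (camera adjusted p = 0.000248; adjusted p = 0.319 with an estimated correlation). NF-kB genes were higher in 17 of 26 cases and lower in 2, in both counts, over all genes and adjusted over the list alone (camera adjusted p = 0.000655; adjusted p = 0.204 with an estimated correlation). IL11 had a log2 fold change of -2.17 in M059K and 1.19 in LN229. Integrated stress response genes were higher in 23 of 42 cases and lower in 11, adjusted over the list alone too (camera adjusted p = 0.00455; adjusted p = 0.337 with an estimated correlation). Ribosome biogenesis genes were higher in 20 of 37 cases and lower in 2 (22 and 2 adjusted over the list alone; camera adjusted p = 0.00036; adjusted p = 0.303 with an estimated correlation). Epithelial markers were higher in 6 of 9 cases and lower in 0 (7 and 0 adjusted over the list alone; camera adjusted p = 0.000909; adjusted p = 0.143 with an estimated correlation). Mitochondrial chaperones and proteases were higher in 10 of 23 cases and lower in 1, adjusted over the list alone likewise (camera adjusted p = 0.0305; adjusted p = 0.394 with an estimated correlation). That last call was lost without M059K control replicate 2 (adjusted p = 0.0731), M059K gamitrinib replicate 1 (adjusted p = 0.069), LN229 control replicate 1 (adjusted p = 0.0966) or LN229 gamitrinib replicate 2 (adjusted p = 0.061), with library size alone (adjusted p = 0.158), and with the preranked camera test (adjusted p = 0.205).

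The difference test did not pass for the heat shock list (11 of 34 higher and 13 lower, 11 and 17 adjusted over the list alone, adjusted p = 0.45) or the NRF2 list (7 of 28 higher, 10 lower, adjusted p = 0.709). Scaled by library size, these lists had 7 higher and 19 lower, and 4 higher and 12 lower. It did not pass for the interferon list either (16 of 35 higher and 5 lower, 17 and 6 adjusted over the list alone, adjusted p = 0.175). Library size scaling gave 11 higher and 7 lower for that list. Without LN229 gamitrinib replicate 2 the interferon list passed (adjusted p = 0.0393). The cytosolic HSP90 genes had differences of -0.02 ± 0.05 (HSP90AA1) and 0.02 ± 0.04 (HSP90AB1), which did not pass (adjusted p = 0.77 and 0.772), except for HSP90AA1 without LN229 gamitrinib replicate 2 (-0.10, adjusted p = 0.0378) and HSP90AB1 with library size alone (-0.10, adjusted p = 0.0165). PKM had a difference of 0.02 ± 0.04 (adjusted p = 0.698), against -0.10 with library size alone (adjusted p = 0.0181). Differences that passed narrowly were those of EIF2AK2 (0.16, adjusted p = 0.0361), ID3 (-0.19, adjusted p = 0.0191) and HERPUD1 (0.20, adjusted p = 0.0458). The EIF2AK2 difference was lost without any single library except M059K gamitrinib replicate 2 (adjusted p = 0.0631 to 0.225 without the others), and the HERPUD1 difference without each of the 8 (adjusted p = 0.0599 to 0.176). The ID3 difference was lost without M059K control replicate 1 (adjusted p = 0.119), LN229 control replicate 2 (adjusted p = 0.0638) or LN229 gamitrinib replicate 1 (adjusted p = 0.0759).

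Among mitochondrial lists, no difference was called for complexes II to IV (6 of 26 higher and 11 lower, 6 and 13 adjusted over the list alone, adjusted p = 0.356), ATP synthase (4 of 18 higher, 6 lower, adjusted p = 0.372) or biogenesis (4 of 25 higher, 5 lower, adjusted p = 0.444). The mitochondrial ribosome had 17 of 76 higher and 16 lower (adjusted p = 0.941), mitochondrial import 5 of 25 higher and 9 lower (adjusted p = 0.372), and the tricarboxylic acid cycle 9 of 23 higher and 6 lower (10 and 8 adjusted over the list alone; adjusted p = 0.907). Neither p53 targets (3 of 29 higher, 9 lower, adjusted p = 0.187) nor the BCL-2 family (8 of 23 higher, 6 lower, adjusted p = 0.809) passed. Autophagy genes had 10 of 44 higher and 17 lower (11 and 17 adjusted over the list alone; adjusted p = 0.356), and kinases 12 of 26 higher and 8 lower (13 and 8; adjusted p = 0.183). The kinase list passed with the preranked camera test (adjusted p = 0.0263). Neural and glial genes had 2 of 26 higher and 8 lower (2 and 7 adjusted over the list alone; adjusted p = 0.237), telomere genes 1 of 22 higher and 3 lower (1 and 2; adjusted p = 0.639), and immediate early genes 11 of 29 higher and 13 lower (adjusted p = 0.579). Markers of microglia had 1 of 5 higher and 0 lower (adjusted p = 0.861), neurons 0 of 12 higher and 4 lower (adjusted p = 0.356), oligodendrocytes 3 of 10 higher and 0 lower (adjusted p = 0.356) and endothelium 2 of 9 higher and 1 lower (adjusted p = 0.372). Some of these directions turned or grew under library size scaling, where none of the lists that follow passed. The mitochondrial ribosome then had 8 genes higher and 21 lower (median -0.08 instead of 0.04), the tricarboxylic acid cycle 3 higher and 8 lower, and the BCL-2 family 6 higher and 9 lower. Autophagy genes had 5 higher and 21 lower, ATP synthase 1 higher and 10 lower, complexes II to IV 3 higher and 15 lower, and biogenesis 3 higher and 10 lower.

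**Figure D3:**
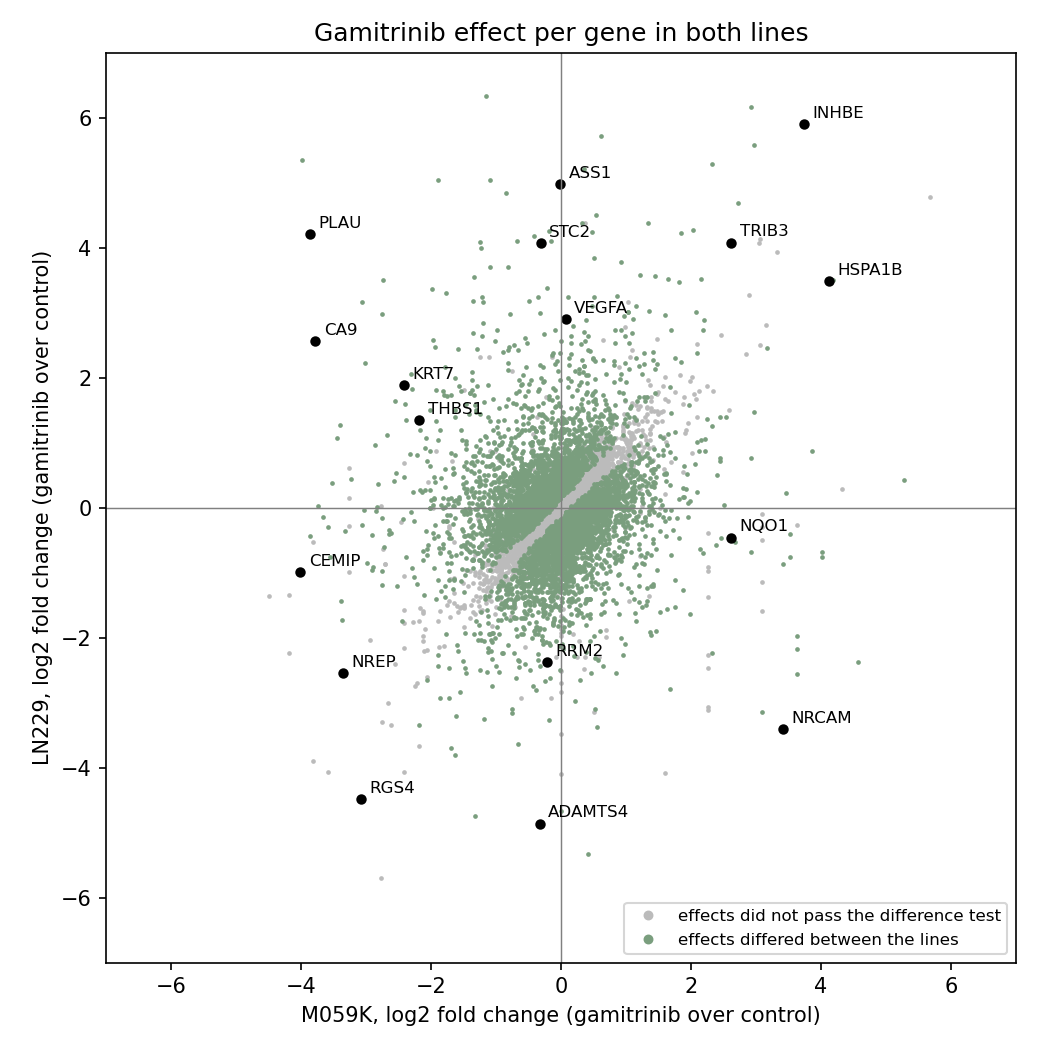
Log2 fold change (gamitrinib over control) in M059K (x axis) and LN229 (y axis) of the 11038 genes with a mean of at least 5 CPM over the 4 groups, green where the difference between the lines passed an adjusted p of 0.05; 3 genes lie outside the axes, which end at 7. PLAU, CA9, KRT7 and THBS1 lie at upper left, HSPA1B and TRIB3 at upper right, and NRCAM and NQO1 at lower right.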

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

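The tests of an excess in control cells, of 5' TOP mRNAs and of exchanged labels were chosen after the results were seen; the tests of GC content and gene length, of pseudogenes and of M059K RNA were not. The test of an excess in LN229 control cells was changed after its values were seen. As first written, it rested on the ratio of the lines in control libraries, and the value of 0.18 met neither bound, so that version decided nothing. A test of library scaling against the median of all genes was dropped, since a scaling shifts every gene alike and so fixed its outcome.

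The effect of gamitrinib differed between the lines, by the test of the difference itself, for 3472 genes with a higher effect in LN229 and 3421 with a lower effect. It also differed for 74 of the 86 named genes, which were chosen partly for large changes and differences, against 49.0% of all tested genes. By the camera test it differed for 16 of 36 lists. None of these list calls held with an estimated correlation, where the smallest adjusted p was 0.0586. All values that follow are LN229 effect minus M059K effect on the log2 scale. List medians below 0 were -1.13 for DNA replication, -0.89 for homologous recombination and Fanconi genes, -0.63 for mitosis, -0.51 for cholesterol genes, -0.25 for the endoplasmic reticulum list and -0.22 for complex I. Medians above 0 were 1.59 for epithelial markers, 1.18 for NF-kB genes, 1.08 for extracellular matrix genes, 0.89 for hypoxia, 0.57 for ribosomal proteins, 0.48 for glycolysis, 0.44 for aminoacyl-tRNA synthetases, 0.41 for the integrated stress response, 0.19 for ribosome biogenesis and 0.16 for mitochondrial chaperones and proteases. Without members that had no reads in a group, the epithelial, NF-kB and stress response medians were 1.99, 1.12 and 0.44.

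Among stress genes the differences were -0.67 for HSPA1A, -0.63 for HSPA1B, -0.52 for DNAJB1, -0.44 for HSP90B1, -1.32 for FKBP5, 0.27 for TRAP1 and 0.74 for LONP1. They were 1.46 for TRIB3, 0.55 for ASNS, 1.11 for DDIT3, 0.56 for ATF4, 4.39 for STC2, 2.17 for INHBE, 2.63 for ADM2 and 2.97 for NUPR1. GARS1 differed by 0.47, VARS1 by 0.69, PDIA4 by -0.86, HERPUD1 by 0.20 and SQSTM1 by 0.20. For NRF2 targets the values were -3.07 for NQO1, -0.23 for FTL, 0.69 for HMOX1 and 0.35 for TXNRD1. For interferon-stimulated genes they were 1.96 for IFI44L, -2.42 for IFIT2, 3.68 for OASL and 0.16 for EIF2AK2. ADM2 was 3.57 without LN229 control replicate 1 and 2.04 without replicate 2. The HERPUD1 call was lost without each of the 8 libraries (0.15 to 0.21), and the EIF2AK2 call without each except M059K gamitrinib replicate 2 (0.11 to 0.17). With library size alone the calls of TRAP1 (0.15), HERPUD1 (0.08), SQSTM1 (0.08) and EIF2AK2 (0.04) were lost.

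For matrix, surface, cytoskeletal and secreted protein genes the differences were 3.02 for CEMIP, 8.08 for PLAU, 6.35 for CA9, 2.80 for ACTA2, 3.53 for THBS1, 1.16 for FN1, 4.31 for KRT7, 1.99 for KRT14, 1.40 for MET, 2.66 for PDGFRB and 3.36 for IL11. For metabolic and hypoxia genes they were 0.78 for LDHA, 1.31 for HK2, 0.39 for OGDH, -0.55 for IDH2, -0.54 for SREBF2, 1.32 for SLC2A1, 2.83 for VEGFA, -0.70 for NDUFS6, -0.44 for COX8A and 0.23 for ATP5F1A. The ATP5F1A call was lost with library size alone (0.12). For proliferation genes they were -0.72 for MKI67, -0.62 for KIF20A, -0.71 for NEK2, -2.16 for RRM2, -1.73 for MCM4, -0.54 for TK1, -1.58 for FANCA and -1.90 for EXO1. Ribosomal and nucleolar genes had 0.58 for RPS12, 0.57 for RPS18, 0.60 for RPL37 and 0.61 for DDX21.

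Other genes had differences of 7.46 for KLHDC7B, 5.00 for ASS1, 3.04 for AKNA, 6.73 for IL1RL1, -4.66 for FREM1, -4.53 for ADAMTS4, -1.17 for EGR1, -1.69 for SPRY4, -1.39 for RGS4, 0.81 for NREP, -6.81 for NRCAM, -6.24 for PTPRZ1 and -0.19 for ID3. The KLHDC7B, IL1RL1 and PTPRZ1 values rest on a group with no reads and so on the prior count of 0.125. In M059K too, KLHDC7B went up from 0.233 to 8.49 CPM, IL1RL1 from 12.3 to 85.6 CPM and AKNA from 13.6 to 34.3 CPM. ASS1 had 14.6 CPM in control and 14.4 CPM in gamitrinib libraries of M059K. PTPRZ1 lost its call without M059K gamitrinib replicate 1 (-3.15), and was -7.15 without replicate 2. KLHDC7B was 6.67 without M059K control replicate 1. NRCAM was -6.06 without M059K control replicate 1 and -8.35 without replicate 2. ASS1 was 5.95 without LN229 control replicate 1 and 4.41 without replicate 2. ID3 lost its call without M059K control replicate 1 (-0.14), LN229 control replicate 2 (-0.17) or LN229 gamitrinib replicate 1 (-0.16), and with upper quartile scaling (-0.14).

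DNA replication genes fell in LN229 and, as a list, did not pass in M059K, where 36 of 57 rose and 6 fell under library size scaling. The LN229 call and that of the difference were lost with an estimated correlation (adjusted p = 0.065 and 0.0586). After the trend with GC content and exon length was removed, the median difference was -1.07, against -0.14 to 0.12 for 10000 random lists matched on expression, which argues against that trend as the whole cause. The median difference was -1.09 to -1.25 under 4 scalings. The list's median log2 ratio of LN229 to M059K was 0.18 in control and -1.03 in gamitrinib libraries. In these groups 37 and 2 of 57 genes were higher in LN229, so LN229 ended below M059K rather than near it. The gamitrinib value nearly follows from the control value and the difference above. It is therefore no separate evidence on an excess of replication transcripts in LN229 control cells. A difference between the lines in cell cycle arrest may underlie the pattern, a hypothesis that these libraries do not test, since no cell counts or cell cycle measurements were analysed here.

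Ribosomal protein genes rose in LN229, a list call lost with an estimated correlation (adjusted p = 0.252). Their median after removal of the GC and length trend was 0.53, above the random range of -0.23 to 0.05, and the 30 genes with at most 5 named pseudogenes had a median of 0.54, against 0.55 for the 42 with more. These values argue against either as the whole cause. Other mRNAs with a 5' TOP motif, whose stability and translation are controlled together with those of ribosomal protein mRNAs, had a median of 0.43 in LN229 (23 of 26 rose, 1 fell), above the random limit of 0.15. A shared change of 5' TOP mRNAs in LN229 is a hypothesis that the value of 0.43 leaves open, since the genes were chosen after the rise was seen and a change in composition of these libraries by RNA class was not tested.

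There were 849 genes that fell in M059K and rose in LN229. M059K RNA in the LN229 gamitrinib libraries would have to reach 23.7% to account for them, but 22 genes abundant in M059K and near absent from LN229 control cells reached a median of 0.136% of their M059K level. Exchanged control and gamitrinib labels in a line would turn the stress lists around, but at least 85.3% of the heat shock and ATF4 lists rose in each line. A difference between the lines in how they respond stays open as a hypothesis; the 0.136% and 85.3% speak only against those explanations.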

How the results depend on the processing

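All alternatives were fixed beforehand. With an estimated correlation, 0 lists passed in either direction in M059K, LN229 or the difference. That version of the test rests on 4 residual degrees of freedom, so a loss need not reflect correlation between genes. For lists with a high estimated correlation it may, as for ribosomal proteins (0.46) and interferon-stimulated genes (0.29). The rotation test fry, which does not compare a list with other genes, called 11 lists higher and 17 lower in M059K, and 15 lower for the difference. With library size alone, 6255 genes rose and 2788 fell in M059K, and 3303 rose and 1318 fell in both lines; 6 named values with a call under either scaling changed sign: MCM4 (0.19), NDUFS6 (0.20), COX8A (0.03) and DDX21 (0.08) in M059K, and the differences of HSP90AB1 (-0.10) and PKM (-0.10). Without a call, the sign also turned for TRAP1 (0.09), FANCA (0.09) and ASS1 (0.19) in M059K and SLC2A1 (0.01) in LN229. The median of all genes shifted by 0.20 in M059K and by -0.12 for the difference under that scaling. With a 1.5-fold minimum, 948 genes rose and 1254 fell in M059K, 1314 and 1378 in LN229, and 1143 and 928 had a higher and lower difference; 363 rose and 343 fell in both lines, and 174 moved in opposite directions, which follows from the stricter hypothesis. Without each library in turn, M059K had 3528 to 4148 genes higher and 3811 to 4322 lower, LN229 3702 to 4316 and 3832 to 4460, and the difference 3080 to 3222 and 3161 to 3312. Genes higher in both lines numbered 1835 to 1889, lower in both 1999 to 2089 and opposite 1287 to 1361. Lists higher and lower numbered 5 to 6 and 7 to 9 in M059K, 9 to 10 and 12 to 12 in LN229, and 9 to 10 and 6 to 6 for the difference. The lone library left in a group was assumed to vary like the other groups. Single-gene calls lost without a library are given above for some printed genes only. Those genes were chosen from these data, so they may look more stable than the tested genes as a whole. DESeq2 called 7597, 7854 and 6186 genes in M059K, LN229 and the difference, where it gave no adjusted p for 273. Same-numbered libraries did not deviate together (r of -0.04 to 0.03). These values give no sign of pairing by number, but they cannot exclude that such libraries were handled together. A replicate block within each line called 8273, 8568 and 6863 genes, and a replicate block shared by both lines 8216, 8501 and 6793. The block within lines ended the call of epithelial markers in LN229 (adjusted p = 0.0628), and both blocks that of the HERPUD1 difference (0.20). At this depth, genes near the floor such as KLHDC7B have no usable fold beyond a lower bound.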

Other observations

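The tests of gene families and of the distance between the lines were chosen after the results were seen. Families were formed from the stems of gene symbols, 235 in all. Of the C2H2 zinc finger genes whose symbols begin with ZNF, 238 of 477 rose and 42 fell in M059K, with a median of 0.33 (camera adjusted p = 3.65e-06; adjusted p = 0.818 with an estimated correlation). The median was 0.54 with library size alone, a scaling that also moved the median of all genes to 0.20. A scaling shifts all genes alike, so that value is no separate support. In LN229, 171 rose and 48 fell (adjusted p = 0.0659), and the difference did not pass (adjusted p = 0.229). The clustered protocadherin beta genes (PCDHB), adhesion genes of neural cells, fell in 15 of 15 cases in LN229 with a median of -1.07 (adjusted p = 0.000137; adjusted p = 0.861 with an estimated correlation). In M059K 11 fell and 0 rose (adjusted p = 0.168), and the difference had a median of -0.63 (adjusted p = 0.0138; adjusted p = 0.954 with an estimated correlation). Members of this cluster are similar in sequence, and how their reads were divided was not examined, so their values are uncertain. The effect of gamitrinib on keratin genes differed between the lines in 11 of 19 cases, each with a higher effect in LN229, and the median difference was 2.71 (adjusted p = 3.34e-05; adjusted p = 0.954 with an estimated correlation). Collagen genes fell in 24 of 39 cases in M059K and rose in 2, with a median of -1.09 (adjusted p = 6.46e-05; adjusted p = 0.818 with an estimated correlation).

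The lines lay nearer to each other after treatment. The median absolute log2 ratio between an LN229 and an M059K library was 0.71 to 0.72 over the 4 pairs of control libraries and 0.63 to 0.66 over the 4 pairs of gamitrinib libraries. Of the 1486 genes that moved in opposite directions, 993 (66.8%) ended nearer to each other, as did 2342 of 4259 (55.0%) that moved in the same direction. Genes with distant starting levels tend to approach each other by chance alone, and this was not tested. Ribosomal protein genes held 3.37 ± 0.03% of gene counts in M059K control and 3.73 ± 0.07% in M059K gamitrinib libraries (SD, n = 2), and 3.10 ± 0.02% and 4.76 ± 0.00% in LN229. These are shares of all gene counts, without TMM scaling. With TMM, 21 of the 72 genes rose and 30 fell in M059K (median -0.03), so the higher M059K share depends on the scaling.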
